A study of Mus musculus with 2 samples.

How the data were processed

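Single-cell RNA was measured with the 10x Genomics 3' v2 protocol in 2 libraries of CD4 T cells sorted from pancreatic islets of NOD mice, 1 Venus-positive and 1 Venus-negative. Per the submitters' processing notes, reads were processed with Cell Ranger 2.2.0 against mm10. The authors deposited one matrix per library with counts of UMIs per gene and barcode for 27998 genes, and these counts were not normalized. The matrices hold only barcodes already called as cells, so empty droplets were not available and free RNA was judged from marker genes. The release of the gene annotation is not given in the sources used here. It held no T cell receptor or immunoglobulin genes, constant or variable, and no Venus gene, and 13 marker genes sought were missing for this reason. Counting UMIs removes PCR copies, and 3' reads give levels per gene but not per isoform. Gene positions came from the GENCODE M21 annotation of mm10, matched by gene identifier, and were found for all 241 genes sought.

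Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept, which left out 4 barcodes in each library. Doublets were scored with Scrublet through scanpy 1.11.5 in each library alone. The top-scoring cells were left out at 0.8% per 1000 barcodes, which marked 53 Venus-positive (2.05%) and 78 Venus-negative cells (2.50%). The remaining 2526 and 3033 cells were clustered together, scaled to 10000 UMIs and log transformed, on 2000 variable genes, 30 principal components and 15 neighbours with Leiden resolution 0.8 (python-igraph 0.11.9, seed 0). Il21, mitochondrial and ribosomal protein genes took no part in clustering, and the annotation had no receptor segments to leave out. No batch correction was applied, because library and sort gate coincide. Of 12 clusters, 10 were CD4 T-like, and they were named from fixed markers, as a rule when at least 3 markers of a class were among the 10 leading genes. The Tfh-like cluster was an exception with 2 leading markers, Tox2 and Cxcr5. It was named because Bcl6, Sostdc1, Ascl2 and Sh2d1a, summed over both libraries, were also higher there than in the other CD4 T-like clusters. The Xcl1-high cluster met no class and was named after a leading gene. The Il7r-high cluster was a second exception: Il7r, Klf2 and S1pr1 are 3 naive or central memory markers, but the Th1 markers Il18r1 and Ccl5 also led it, and it was kept apart from the naive or central-memory-like class. A cluster with acinar transcripts and a CD3-low cluster were left out of the comparisons. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9 were used.

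UMIs were summed per library over CD4 T-like cells and scaled to CPM. With 1 library per group no test was run, and no p-value or standard error is given, since cells are not replicates. Ratios have exact conditional binomial intervals, levels have Poisson intervals, and shares of cells have exact Clopper-Pearson intervals, all at 95% and for counting error only. A gene was called apart at 2-fold or more with an interval that excluded 1, among genes with at least 100 summed UMIs. List members needed 30 summed UMIs and 1.5-fold. A gene at 0 UMIs in one library was given a ratio against a floor of 3 UMIs in that library. The lower limit of its exact interval is printed beside it. Shares of cells with a UMI were compared after thinning each cell to 2400 UMIs, the 10th percentile of the shallower library rounded down, and shallower cells were left out.

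The gene lists, class markers, thresholds and alternatives were fixed before the data were examined. The 29 lists were 18 of cell state and 11 of other cell types. The state lists were Tfh, Th1, Th2, Th17, Treg, naive or central memory, cytotoxic, inhibitory receptor, anergy, T cell receptor-induced, dissociation stress, type I interferon response, cell cycle, tissue residency, cytokines, chemokine receptors, glycolysis and oxidative phosphorylation. The other lists covered CD8 T, gamma-delta or innate-like T, natural killer, B, plasma, macrophage, dendritic, endocrine, acinar, endothelial or stromal, and erythroid cells. The genes named were the 15 highest and 15 lowest ratios among genes with at least 100 summed UMIs and 20 CPM in the higher library. Il21, mitochondrial, ribosomal protein and receptor segment genes and unnamed transcripts were not eligible. Within a class with at least 100 cells of each library the 8 highest and 8 lowest were named, and 2 to 4 members of each list. The random lists numbered 10000 per list, drawn within 20 expression bins. Genes described by class and by their top 10 cells were chosen after their values were seen.

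The alternatives were other cell filters (200 genes and 20%, or 800 genes and 5%), doublets kept, all barcodes, TMM scaling (edgeR 4.0.16, R 4.3.3) and DESeq2 1.42.0 size factors, other UMI minimums and fold limits, thinned cells, 2 other clustering resolutions, 15 components, other clustering genes, and each library clustered alone. A further 2 cell sets were added after the data were seen. The ratio step was tested on Poisson counts simulated from the summed counts, in which 200 genes were given known folds. Of the changed genes, 100% of those 4-fold apart, 94% of those 2.5-fold apart and 0% of those 1.5-fold apart were called, and 0% of unchanged genes. The intervals held the true ratio for 95.3% of unchanged genes, and 6% of 200 random lists fell outside the central 95%. The intervals assume the same Poisson counting, so this coverage checks the computation only. UMIs gathered in few cells were not simulated, and the coverage says nothing about genes of that kind.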

Results

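Islet-infiltrating CD4 T cells were profiled from 9 to 12 week old female NOD mice, a strain that develops autoimmune diabetes spontaneously. The strain characteristic, NOD.Il21V/+, names an Il21 reporter allele, read out through the fluorescent protein Venus. The protocol text writes NOD.Il2V/+ instead, and the characteristic is followed here. IL-21 is a helper T cell cytokine that acts on B cells and CD8 T cells. Per the labels, islets were picked by hand, and CD4 T cells were sorted by Venus signal after staining for CD4, CD8, the leukocyte marker CD45.1, the B cell marker CD19 and the dendritic cell marker CD11c. Each sort gave 1 single-cell RNA library. The Venus-positive library held 2583 barcodes and 13198239 UMIs (counted RNA molecules), with a median of 3931 UMIs and 1486 genes per barcode. The Venus-negative library held 3115 barcodes and 12058163 UMIs, with medians of 3645 and 1252. UMIs per barcode ran from 2024 to 37025 and from 1104 to 20261. The comparisons used 2499 Venus-positive and 2976 Venus-negative CD4 T-like cells, with 12764455 and 11429946 UMIs. With 1 library per sort there was no replicate and no test, so no difference below was set against animal or library error. Intervals are 95% and cover counting error only, and the number of mice behind each library is not stated in the labels. Levels are CPM, a gene's UMIs scaled to the same total in both libraries.

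The first comparison asked whether Il21 RNA separated the libraries as the reporter gate did. Il21 (ENSMUSG00000027718, mm10 chromosome 3, 37222759 to 37232636, minus strand, protein coding) gave 1308 UMIs in the Venus-positive library and 2 in the Venus-negative one. These were 102 and 0.175 CPM, a ratio of 586 (exact conditional binomial interval 162 to 4841). Because the gate selected on a reporter of this gene, the ratio checks the labels and is not a finding. At a depth of 2400 UMIs per cell, Il21 was seen in 20.5% of 2295 Venus-positive cells (exact binomial interval 18.8 to 22.2). The background share, in the Venus-negative library at the same depth, was 0.0373% of 2680 cells. Without thinning the shares were 32.2% and 0.0672%, at median depths of 3916 and 3627 UMIs. The Venus transcript itself is not in the deposited annotation and was not measured.

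The second comparison asked which other genes separated the IL-21 reporter-positive cells from the other islet CD4 T cells. Follicular helper, inhibitory receptor, cytokine and cell cycle genes were mostly higher in the Venus-positive library. Genes of naive T cells and Foxp3, the lineage factor of regulatory T cells, were higher in the Venus-negative one. Sostdc1, a secreted BMP and Wnt antagonist made by follicular helper cells (ENSMUSG00000036169, chromosome 12, 36314139 to 36318452), had 1043 UMIs against 0. Against a floor of 3 UMIs per library it was 311-fold higher, and the lower limit of its interval was 253. Dapl1, abundant in naive T cells (ENSMUSG00000026989, chromosome 2, 59484653 to 59505020), had 6 against 2157 UMIs and was 401-fold lower (184 to 1095). Foxp3 (chromosome X, 7573644 to 7595245) had 16 against 648 UMIs and was 45.2-fold lower (27.6 to 79.6).

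Of 8873 genes with at least 100 UMIs, 824 were at least 2-fold higher and 340 at least 2-fold lower in the Venus-positive library with an interval that excluded 1. Together they made up 13.1% of the genes, and 70.8% of them were higher in the Venus-positive library. That split depended on scaling. TMM gave 660 and 449 genes, of which 59.5% were higher in the Venus-positive library, and DESeq2 size factors gave 664 and 444, or 59.9%. The median log2 ratio of all genes was 0.16 by total UMIs and 0.01 with either alternative, so log2 values over all CD4 T-like cells are to be read against a shift of 0.16. Ribosomal protein genes, which take no part in the named genes, held 29.8% of Venus-positive and 37.5% of Venus-negative UMIs.

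Spp1, the matrix protein osteopontin (chromosome 5, 104435118 to 104441050), had 796 UMIs against 0 and was 238-fold higher against the floor (lower limit 193). Cxcl13, the chemokine ligand of CXCR5 (chromosome 5, 95956951 to 95961068), had 664 UMIs against 0 and was 198-fold higher against the floor (lower limit 161). Ccl3, a ligand of CCR5 (chromosome 11, 83647844 to 83649355), had 2868 UMIs against 23, a ratio of 112 (74.3 to 176). These 3 genes rested on few cells: the 10 highest cells held 46.5%, 46.7% and 49.4% of their UMIs, and UMIs were seen in 120, 99 and 286 of the 2499 cells. Foxb1, a forkhead transcription factor, had 326 UMIs against 2 (146-fold, 40.1 to 1210), and the cell cycle inhibitor gene Cdkn2b had 266 against 3 (79.4-fold, 26.9 to 387). Tox2, a transcription factor of follicular helper cells, was 17.5-fold higher (13.4 to 23.1) and was seen in 29.3% of Venus-positive cells. Nrgn (43.4), Zeb2 (29.5), Plekho1 (21.5), Fam20a (20.4), Sccpdh (18.9), Cenpm (18.7), Ccna2 (18.2) and Ube2c (17.3) completed the 15 highest ratios. The last 3 are genes of dividing cells.

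On the other side, Igfbp4 had 10 against 2896 UMIs and was 323-fold lower (176 to 675). Sell, the lymph node homing receptor L-selectin, was 46.9-fold lower (35.9 to 62.4), and Satb1, a chromatin organiser of T cell development, was 23.1-fold lower (19.3 to 27.7). Cpne4 had 3 against 254 UMIs, 94.6-fold lower (32.0 to 462). Itgae, the CD103 integrin subunit, was 15.4-fold lower (10.2 to 24.5). The others, by fold lower, were Pdlim4 (176), Vipr1 (66.7), Nacc2 (37.8), Irgc1 (29.5), Ifngr2 (24.2), Treml2 (16.6), St8sia6 (15.6) and Als2cl (14.2).

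**Figure D1:**
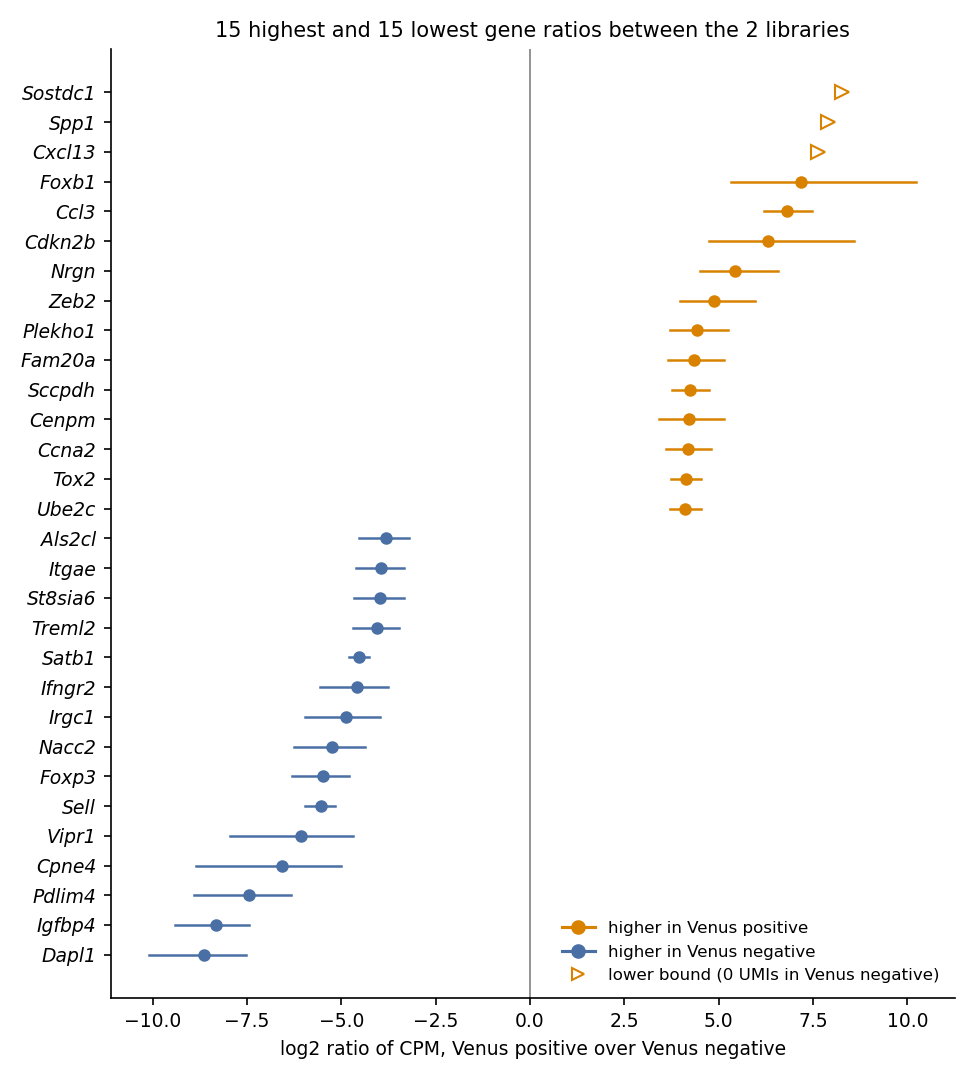
Log2 ratio of CPM, Venus positive over Venus negative, for the 15 genes with the highest and the 15 with the lowest ratio (1 library per group). Points are ratios with 95% counting intervals and open triangles are lower bounds for Sostdc1 (8.28), Spp1 (7.89) and Cxcl13 (7.63), while Dapl1 sits lowest at -8.65.

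The gene lists gave the same comparison by function. Each list's median log2 ratio was placed among 10000 random lists of the same size and expression, which describes these libraries only. Of 19 follicular helper (Tfh) genes, 18 were at least 1.5-fold higher and 1 lower in the Venus-positive library, with a median of 2.24 (percentile 100). Pdcd1, which encodes the inhibitory receptor PD-1, was at 259 against 24.4 CPM (10.6-fold, 9.38 to 12.0). Cxcr5, the receptor that guides cells to B cell follicles, was at 46.8 against 4.99 CPM (9.38-fold, 7.14 to 12.5), and Bcl6, the Tfh lineage factor, at 28 against 5.95 CPM (4.70-fold, 3.62 to 6.19). Il6ra was the lower member, with a ratio of 0.497 (0.454 to 0.543). All 16 cell cycle genes were higher (median 2.34, percentile 100), with Mki67 at 8.76-fold (7.09 to 10.9).

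Of 10 inhibitory receptor genes, 9 were higher and none lower, with a median of 2.02 (percentile 100). Lag3 was at 1002 against 121 CPM (8.30-fold, 7.85 to 8.78), and Havcr2, which encodes TIM-3, was 10.3-fold higher (6.78 to 16.3). Of 9 anergy-associated genes, 7 were higher and none lower (median 1.45, percentile 100), among them Tbc1d4 at 9.99-fold (9.27 to 10.8) and Egr2 at 6.8-fold (5.30 to 8.83). Of 12 genes induced by T cell receptor signalling, 6 were higher and 2 lower (median 0.57, percentile 99.5). Irf4 was 5.31-fold higher (4.26 to 6.67), whereas the early activation gene Cd69 had a ratio of 0.635 (0.603 to 0.668). Of 10 tissue residency genes, 6 were higher and 3 lower (median 1.43, percentile 100), with Cxcr6 at 4.69-fold (4.28 to 5.13).

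Cytokine genes were higher in 8 of 12 cases and lower in none (median 1.22, percentile 100). Ifng stood at 140 against 18.8 CPM (7.46-fold, 6.47 to 8.63), Il10, an anti-inflammatory cytokine, at 68.6 against 17.9 CPM (3.83-fold, 3.28 to 4.48) and Tnfsf11 at 115 against 11.7 CPM (9.85-fold, 8.25 to 11.8). Of 12 Th1 genes, 9 were higher and 2 lower (median 1.25, percentile 100), with Tbx21, the Th1 lineage factor, at 2.38-fold (1.88 to 3.03) and Hopx at a ratio of 0.342 (0.271 to 0.428). Cytotoxic genes went both ways, 6 higher and 4 lower of 13 (median 0.54, percentile 97.4). Gzmk and Ccl4 were 5.17-fold (4.44 to 6.06) and 12.0-fold (11.1 to 13.0) higher, while Gzmb and Prf1 had ratios of 0.414 (0.331 to 0.515) and 0.159 (0.0648 to 0.341). Chemokine and migration receptors also divided, 6 higher and 4 lower of 13 (median 0.59, percentile 98.2).

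Of 14 naive or central memory genes, 12 were lower in the Venus-positive library and none higher, with a median of -3.17 (percentile 0). Lef1 had a ratio of 0.0911 (0.0843 to 0.0984) and Il7r 0.109 (0.0971 to 0.121), whereas Tcf7, a factor shared by naive and follicular helper cells, was at 261 against 277 CPM. Of 16 regulatory T cell genes, 8 were lower and 5 higher (median -0.63, percentile 0). Il2ra had a ratio of 0.478 (0.399 to 0.572), Ikzf2 was at 332 against 329 CPM, and Itgb8 was 3.68-fold higher (2.97 to 4.60). That median was above 0 with a minimum of 300 UMIs, since members that were lower, such as Klrg1 and Lrrc32, then had too few UMIs to enter. It was also above 0 with thinned cells, for which the cause was not tested. Of 5 Th2 and 5 Th17 genes measured, none was higher and 2 of each were lower, with medians of 0.02 (percentile 31.9) and -0.14 (percentile 16.1).

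Type I interferon response genes were lower in 8 and higher in 2 of 14 cases (median -0.68, percentile 0), with Ifit3 at a ratio of 0.354 (0.312 to 0.402) and Ifi27l2a at 1.68 (1.66 to 1.71). Dissociation stress genes, a sign of sample handling, were lower in 7 of 12 cases and higher in none (median -0.69, percentile 0), with the heat shock gene Hspa1a at 0.449 (0.434 to 0.464). Glycolysis genes were higher in 6 and lower in 1 of 15 cases (median 0.44, percentile 97.6), and Gapdh was 2.35-fold higher (2.29 to 2.42). Oxidative phosphorylation genes had 2 of 14 members higher and none lower (median 0.39, percentile 96.0).

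**Figure D2:**
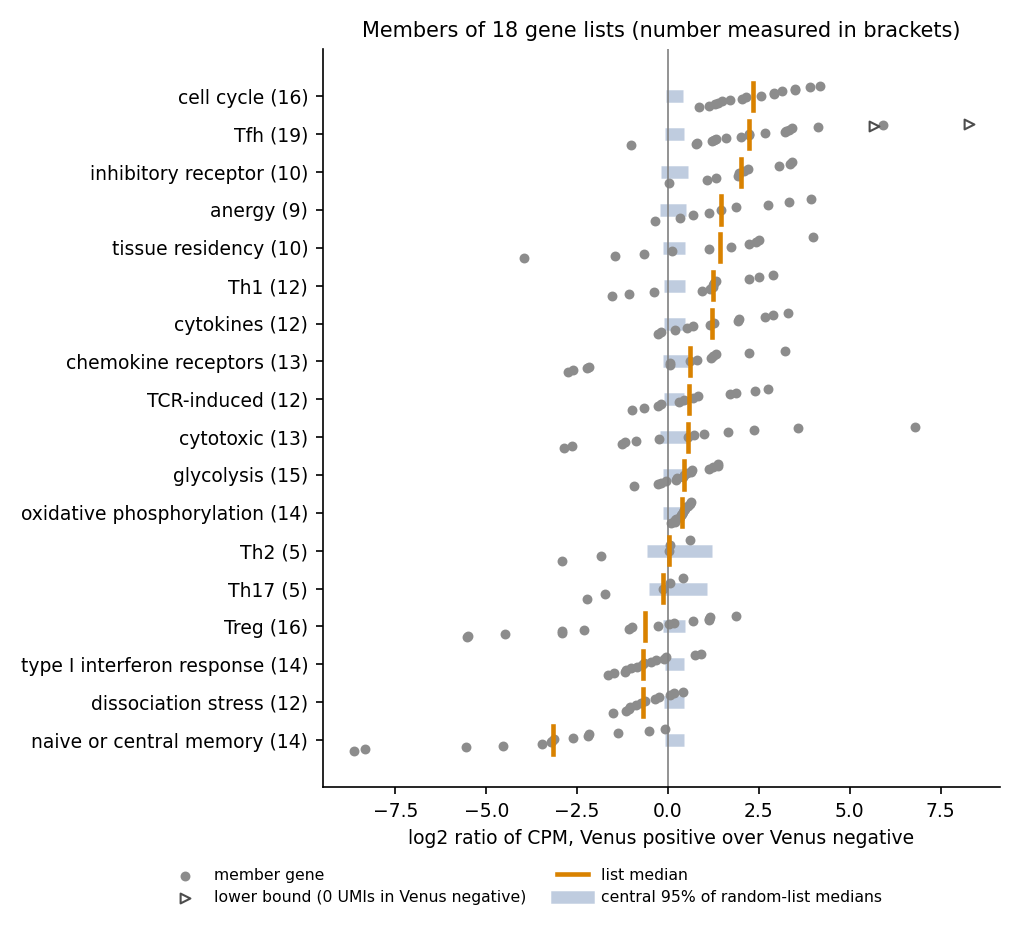
Log2 ratio of CPM, Venus positive over Venus negative, for the measured members of 18 gene lists (dots), with each list's median (vertical bar) and the central 95% of medians of random lists (shaded). The medians run from 2.34 for cell cycle genes to -3.17 for naive or central memory genes.

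Lists of other cell types gave the following sums in the CD4 T-like cells. The 13 exocrine acinar genes summed to 89.9 against 101 CPM, and none of 12 measured members was 1.5-fold apart (median -0.20, percentile 4.62). B cell genes summed to 8.93 against 22.1 CPM, and all 3 measured members were lower (median -1.29, percentile 1.73). Of the list's 253 Venus-negative UMIs, Cd74 had 173 and H2-Aa 35. Both are genes of MHC class II presentation that also led the CD3-low cluster, so the sum is not specific to B cells. The 2 measured macrophage genes, Apoe and Cd68, were 3.77-fold (2.26 to 6.59) and 6.44-fold (3.8 to 11.6) higher, with the list at 16.0 against 4.02 CPM. Apoe rested on few cells, with UMIs in 21 Venus-positive and 19 Venus-negative cells and 86.2% of its Venus-positive UMIs in 10 cells. Of 4 endocrine genes, Gcg alone was higher, by 2.17-fold (1.14 to 4.39). It had 34 against 14 UMIs, in 23 and 8 cells, with 61.8% of its Venus-positive UMIs in 10 cells. The list stood at 12.1 against 8.05 CPM (median 0.38, percentile 56.9). CD8 T cell genes were at 2.90 against 6.91 CPM, with the measured member Cd8b1 lower. Dendritic cell genes summed to 47.9 against 210 CPM, endothelial or stromal genes to 41.8 against 78.0 CPM and plasma cell genes to 53.7 against 37.3 CPM. Each of these lists had 1 measured member, which T cells also make: Ccr7 (0.222, 0.203 to 0.243), Pecam1 (0.515, 0.461 to 0.575) and Xbp1 (1.46, 1.29 to 1.65). No natural killer, gamma-delta T or erythroid marker reached 30 UMIs, and natural killer genes summed to 2.35 against 1.40 CPM, gamma-delta T or innate-like genes to 0.705 against 0.700 CPM, and erythroid genes to 0 UMIs in both, which allows 0.235 and 0.262 CPM.

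The third comparison asked which kinds of cell made up each sort, with clusters formed without Il21 and named from fixed markers. Tfh-like cells, led by Tox2 and Cxcr5, were 46.8% of Venus-positive cells (44.8 to 48.8) and 1.24% of Venus-negative cells (0.877 to 1.71). The Th1- and Tr1-like cluster had markers of both Th1 and Tr1 (IL-10-producing type 1 regulatory) cells, led by Ccl3, Ccl4, Cxcr6, Ccl5, Il10 and Lag3. It held 31.0% (29.2 to 32.9) and 0.235% (0.0946 to 0.484). Of its 775 Venus-positive cells, 227 had an Il10 UMI and 329 an Ifng UMI. Whether single cells carried both kinds of marker was not tested, so the cluster may be a mixture. Naive or central-memory-like cells were 0.0400% (0.00101 to 0.223) and 43.6% (41.8 to 45.4), and Treg-like cells 0.120% (0.0248 to 0.350) and 17.2% (15.8 to 18.6).

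A cluster led by the chemokine gene Xcl1, Nrgn and Tnfrsf9 matched no fixed class and held 9.04% of Venus-positive cells (7.95 to 10.2) and 0.470% of Venus-negative cells (0.257 to 0.788). Cycling cells were 7.48% (6.48 to 8.59) and 0.403% (0.209 to 0.703). Cells of the same class were not alike in Foxp3 between the libraries. In the Venus-negative library, 8 of 12 cycling, 6 of 14 Xcl1-high and 6 of 37 Tfh-like cells had a Foxp3 UMI. In the Venus-positive library 4 of 187, 0 of 226 and 1 of 1170 did. An Il7r-high cluster with naive and Th1 markers held 1.08% (0.713 to 1.57) and 19.5% (18 to 20.9). Interferon-response cells, from 2 clusters, were 4.40% (3.63 to 5.28) and 17.4% (16.1 to 18.9). Since 96.7% of cells lay in a cluster in which their own library held the majority, sort gate and library could not be separated in these shares, and a cluster from 1 library need not be a type of its own. In 8 of 11 alternative clusterings the Xcl1-high cells formed no class of their own, and the Tfh-like share of Venus-positive cells was then 52.2% to 58.5%. The Treg-like share of Venus-negative cells was as low as 5.17% at the coarsest clustering.

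**Figure D3:**
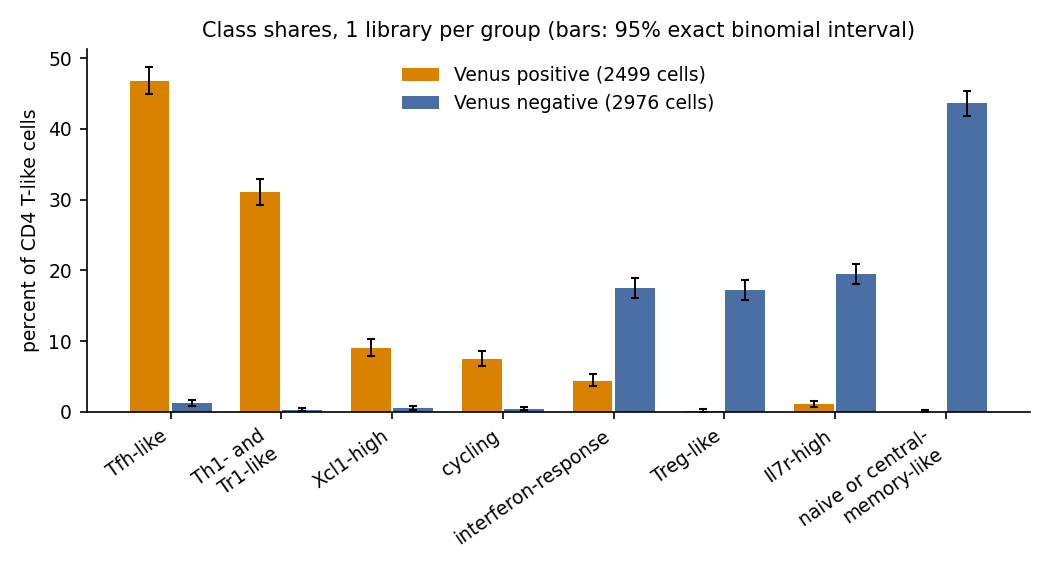
Percent of CD4 T-like cells of each library in 8 classes, with 95% exact binomial intervals (2499 Venus-positive and 2976 Venus-negative cells, 1 library each). Tfh-like (46.8%) and Th1- and Tr1-like cells (31.0%) led the Venus-positive library, and naive or central-memory-like cells (43.6%) the Venus-negative one.

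At 2400 UMIs per cell, the key markers were seen in the following shares of cells. Pdcd1 was seen in 39.9% of Venus-positive and 4.40% of Venus-negative cells, Cxcr5 in 10.2% and 1.12%, Bcl6 in 6.36% and 1.72%, and the costimulatory receptor gene Icos in 34.8% and 11.7%. Lag3 was seen in 69.2% and 7.5%, the transcription factor gene Maf in 65.1% and 16.1%, Ifng in 21.7% and 3.43%, and Il10 in 8.06% and 1.72%. Foxp3 was seen in 0.218% and 8.10%, Sell in 0.566% and 34.3%, Ccr7 in 9.89% and 36.2%, and Tcf7 in 38.2% and 45.9%. Mki67 was seen in 6.84% and 0.970%. The depth left out 204 Venus-positive and 296 Venus-negative cells, and the shares count cells with a UMI rather than cells expressing the gene.

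The fourth comparison addressed the heterogeneity of IL-21-expressing cells named in the series title. Within the Venus-positive library Il21 was found in each class with more than 3 cells. The Th1- and Tr1-like cells had the highest level, 156 CPM (Poisson interval 143 to 171), with UMIs in 281 of 775 cells. Tfh-like cells had 102 CPM (93.3 to 111), with UMIs in 336 of 1170 cells. The ratio between these classes was 1.53 (1.35 to 1.74). Interferon-response cells had 118 CPM (91.1 to 151), Xcl1-high cells 73.1 (59.4 to 89.0), Il7r-high cells 67.7 (24.8 to 147, from 6 UMIs) and cycling cells 49.1 (40.9 to 58.4). Cycling cells were the deepest, at a median of 13391 UMIs, so their lower CPM does not mean fewer Il21 UMIs per cell: 73 of 187 had one. Xcl1-high cells were also deeper than Tfh-like cells, at medians of 5156 and 3681 UMIs, and 30.5% and 28.7% of them had an Il21 UMI. The order of classes therefore holds for CPM only. The Venus-negative library held 1 Il21 UMI in Xcl1-high and 1 in cycling cells. In its Treg-like cells a count of 0 allows up to 1.55 CPM, and in its naive or central-memory-like cells up to 0.610 CPM.

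**Figure D4:**
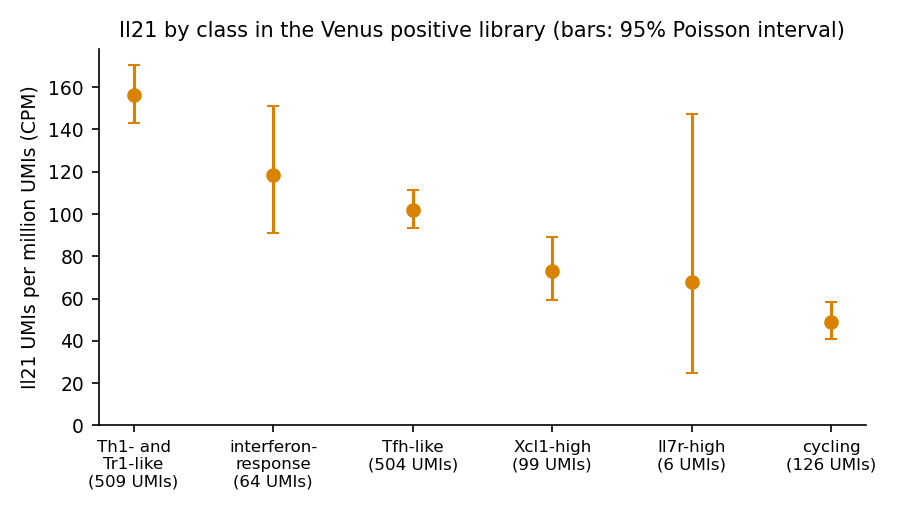
Il21 CPM in 6 classes of the Venus-positive library, with 95% Poisson intervals for counting error (UMI counts under each class name). Th1- and Tr1-like cells (156 CPM) were above Tfh-like cells (102 CPM), and cycling cells were lowest (49.1 CPM).

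The fifth comparison asked what differed within a class. The interferon-response class alone held at least 100 cells of each library (110 and 519). Its Venus-positive cells had higher Cd200 (24.2-fold, 16.5 to 36.5), Tbc1d4 (19.3-fold, 14.8 to 25.6) and Lag3 (18.6-fold, 14.1 to 24.7), all higher in the Venus-positive library as a whole. They also had higher Gpm6b (30.6-fold, 16.8 to 61.3), Ifi202b (25.2-fold, 15.7 to 42.6), Rgs16 (18-fold), Cybb (14.3-fold) and Ptpn11 (12.6-fold). The 8 lowest genes included 4 of the naive or central memory list. Igfbp4 had 0 against 745 UMIs (66.9-fold lower against the floor, lower limit 54.3), and Dapl1 was 44.3-fold lower against the floor (lower limit 35.9). Satb1 and Sell were 18.2-fold (9.54 to 40.1) and 17.8-fold (9.61 to 37.3) lower. Nacc2 (32.3-fold, 5.69 to 1288), Pik3ip1 (28.3-fold), Pdlim4 (18.6-fold against the floor, lower limit 15.0) and Atp1b1 (13.9-fold) completed the 8. Of 2702 genes, 154 were at least 2-fold higher and 143 lower, and with TMM scaling 134 and 175. The class joins 2 clusters that the libraries filled unequally (108 and 55 cells in one, 2 and 464 in the other), so these ratios include a difference in mixture.

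Because naive cells filled much of the Venus-negative library alone, the ratios were taken again in 2 smaller sets of cells, chosen after the class shares were seen. The first set left out naive or central-memory-like and interferon-response cells (2388 against 1160 cells). Of its Venus-negative cells, 511 were Treg-like and 579 Il7r-high, so its ratios compare in large part with Treg-like cells and depend on that mixture. In this set Tfh genes were still higher, 15 of 19 with none lower (median 1.98, percentile 100). Inhibitory receptor genes (8 of 10 higher, median 1.22), anergy-associated genes (5 of 9, median 0.76) and genes induced by T cell receptor signalling (5 of 12, 2 lower, median 0.31) had smaller medians than over all cells. Il10 was 1.70-fold higher (1.45 to 2.00), Lag3 3.58-fold (3.38 to 3.8) and Ccl4 5.22-fold (4.81 to 5.68), while the inhibitory receptor gene Ctla4 was at 192 CPM in both libraries. Th17 genes were lower in 5 of 5 cases (median -1.07, percentile 0.09) and Th2 genes in 3 of 5 (median -1.08, percentile 0.04). Beside these, 7 of 12 acinar genes were lower (median -0.72, percentile 0.02). Both measured members of the B cell list, which is not specific to B cells, were lower too (median -2.66). The median log2 ratio of all genes in this set was 0.05.

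Leaving out Treg-like and cycling cells as well kept 2198 Venus-positive and 637 Venus-negative cells. Of the latter, 579 were Il7r-high cells, whose leading genes include the naive or memory genes Il7r, Klf2 and S1pr1 beside the Th1 genes Il18r1 and Ccl5. Tfh genes were higher in 16 of 19 cases with none lower (median 2.10), against a median over all genes of 0.11. Inhibitory receptor genes (9 of 10, median 2.02), anergy-associated genes (6 of 9, median 1.505) and genes induced by T cell receptor signalling (8 of 12, 1 lower, median 0.82) were also higher. Il10 was 25.5-fold higher (12.9 to 59.2), Lag3 25.8-fold (21.4 to 31.3) and Ccl4 60.4-fold (42.9 to 87.8), in a set without the Treg-like cells that held 146 of the 205 Venus-negative Il10 UMIs. These 3 genes are leading genes of the Th1- and Tr1-like cluster (775 Venus-positive and 7 Venus-negative cells), and Tox2 and Cxcr5 of the Tfh-like cluster (1170 and 37). Their folds in both sets therefore follow in part from how the clusters were formed. Th1 genes divided in both sets, 4 higher and 3 lower of 12 (medians 0.17 and 0.15, percentiles 82.5 and 63.0). In the 2 sets, medians were 0.45 and 0.51 for cytokines (6 of 12 higher in each), 0.38 and 0.97 for tissue residency, 1.67 and 0.79 for cell cycle, 0.20 and 0.17 for cytotoxic and 0.26 and 0.27 for glycolysis genes. Chemokine and migration receptors turned, at -0.31 (3 higher and 5 lower of 12) in the first and 0.81 (4 higher and 2 lower of 11, percentile 99.8) in the second. Treg genes were at -1.75 and 0.96, the second without the Treg-like class by construction. That set was not free of Foxp3: UMIs were seen in 17 of its 579 Venus-negative Il7r-high cells. Naive genes were at -2.50 and -2.60, interferon response genes at -0.52 and -0.43, dissociation stress genes at -0.49 and -0.39 and oxidative phosphorylation genes at 0.26 and 0.20. In the second set 3 of 3 Th17 genes were lower (median -1.83), none of 3 Th2 genes was called either way (median -0.48), and no acinar gene was apart (median -0.30). Both measured macrophage genes were higher in each set (medians 1.78 and 2.21). Ifng in that set was 2.54-fold higher (2.16 to 3.01), while Tbx21 had a ratio of 0.824 (0.624 to 1.10) and Il18r1 0.285 (0.245 to 0.332). Of 8258 and 7449 genes, 426 and 486 were higher and 209 and 147 lower in the 2 sets, and 402 and 372 of the higher and 149 and 101 of the lower genes were also so over all CD4 T-like cells.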

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

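The 2 tests on acinar transcripts below were chosen after the result was seen, and the marker test on the CD3-low cells before it.

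The comparisons left out 2 clusters, whose values are given here because they lie outside the main measurement. A cluster led by digestive enzyme genes of exocrine pancreas (Cela2a, Ctrb1, Amy1, Try4, Pnlip) held 27 of 2526 clustered Venus-positive cells, or 1.07% (0.706 to 1.55). It held 42 of 3033 Venus-negative cells, or 1.38% (1.00 to 1.87). Its cells carried Cd3e at 755 CPM in the Venus-positive library, against 753 CPM in the other T cells, and at 455 against 481 CPM in the Venus-negative library. Acinar genes took 0.937% and 1.35% of its UMIs in the 2 libraries. Acinar RNA spread evenly over all droplets would leave, over all clusters, 1.00 Venus-positive and 0.487 Venus-negative cells with at least 10 acinar UMIs, but 29 and 40 were seen, 28.9 and 82.1 times as many. At 5 UMIs, 69 and 67 cells were seen where even spread gives 39.5 and 38.2, 1.75 times as many in both libraries. The limit of 10 was set after both limits had been tried, and at 5 the same bounds (within 3-fold for even spread, over 10-fold against it) would have favoured even spread. Even spread is therefore argued against only for cells with many acinar UMIs, up to 245 and 647 in a single cell, and low counts stay open to it. Doublets of a T cell and a whole acinar cell would carry more RNA, but the cluster's median UMIs per cell were 0.938 and 0.995 times those of the other T cells. What stays open, and was not tested, is whether acinar fragments or granules on single T cells may be the source. No biological explanation was tested.

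A CD3-low cluster held 15 of 3033 clustered Venus-negative cells, or 0.495% (0.277 to 0.814), and 0 of 2526 Venus-positive cells, which allows up to 0.119%. Its leading genes were MHC class II genes, with H2-Aa 2891-fold (2053 to 4196) and Cd74 803-fold (680 to 954) above the CD4 T-like cells of the same library. Cd3e had 0 UMIs, while Cd4 was 1.71-fold higher (1.11 to 2.53). Rorc, the lineage factor of type 3 innate lymphoid cells, was 48.7-fold higher (21.7 to 99.3) and Il7r 4.44-fold higher (3.45 to 5.63). One hypothesis is that these are CD4-bearing lymphoid tissue inducer cells or other type 3 innate lymphoid cells, which lack the T cell receptor complex. Of 8 further marker genes not looked at before, 5 were at least 2-fold higher with an interval that excluded 1: Kit (664-fold, 127 to 6556, from 7 UMIs), Id2 (7.44-fold, 6.01 to 9.12), Rora (8.25-fold, 4.84 to 13.2), Il1r1 (101-fold, 39.5 to 238) and Lta (11.4-fold, 4.83 to 23.2). Ltb was 1.83-fold higher (1.53 to 2.17), Ahr had 1 UMI, and Tnfsf11 had 0 UMIs, which allows up to 49.8 CPM. T cells also make several of these genes, among them Id2, Rora, Lta and Ltb. The CD4 stain would let such cells through because no CD3 stain is named, whereas CD19 and CD11c gates, if used to exclude, would remove most B cells and dendritic cells. With 15 cells from 1 library the identity may still be another MHC class II-bearing cell, and 5 of 8 markers was the lowest number that met the bound set beforehand.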

How the results depend on the processing

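The sets without naive-like and interferon-response cells, and of the remaining conventional clusters (also without Treg-like and cycling cells), were chosen after the data were seen. No paired analysis was possible because each sort gave 1 library, and no library could be left out. The Il21 ratio stayed above 1 in 8 of 8 alternatives (229 to 626). Tfh genes had a median above 0 in 11 of 11 (1.98 to 2.59), with 1.98 without naive-like and interferon-response cells, and naive genes stayed below 0. The naive median was -3.32 with TMM and with DESeq2, -2.97 with thinned cells, and -2.50 and -2.60 in the 2 added cell sets. The Treg median was above 0 at a minimum of 300 UMIs (0.16), where low members had too few UMIs to enter. It was also above 0 in the remaining conventional clusters (0.96), where Treg-like cells were left out, and with thinned cells (0.35), for which the cause was not tested. It was -1.75 without naive-like and interferon-response cells. Counts of genes higher in the Venus-positive and the Venus-negative library follow from the limits used: 1511 and 767 with no minimum of UMIs, 487 and 188 with a minimum of 300, 1730 and 734 at 1.5-fold, 408 and 160 at 3-fold. They were 426 and 209 without naive-like and interferon-response cells (402 and 149 shared with all cells), and 486 and 147 in the remaining conventional clusters. The Tfh-like share of Venus-positive cells was 58.5% at resolution 0.4, 53.1% at 1.2, 54.3% with 15 components, 53.6% with Il21 kept, 55.7% with 1000 variable genes, 54.6% without cell cycle genes, 58.2% with thinned cells and 52.2% with the looser filter; in these 8 no Xcl1-high class formed. The Treg-like share of Venus-negative cells was 5.17% at resolution 0.4, 10.5% with 1000 genes and 13.9% with thinned cells. The naive share was 50.9% at resolution 0.4, 47.2% without cell cycle genes and 50.6% with each library alone. For these shares the cause was not tested. Il21 was seen in 11.8% of Venus-positive cells at 1200 UMIs and in 32.2% without thinning, as fewer or more UMIs allow. The Th2 median, on 5 genes or fewer, was below 0 with TMM (-0.14), DESeq2 (-0.13), no minimum (-0.0691), every barcode (-0.0280), doublets kept (-0.0579) and the 2 added sets (-1.08 and -0.48). The Th17 median was above 0 at a minimum of 300 (0.0541) and with thinned cells (0.14), but -1.07 and -1.83 in the 2 added sets. The chemokine receptor median was -0.31 without naive-like and interferon-response cells and 0.81 in the remaining conventional clusters. Il21 in Th1- and Tr1-like cells stayed above that in Tfh-like cells in 7 of 7 clusterings (152 to 168 against 94.2 to 99.2 CPM). Among values not central to a comparison, 53 class shares moved beyond their interval (19 higher, 34 lower), 59 list medians moved without a change of sign (13 higher, 46 lower), and 82 shares of cells with a UMI moved with depth (41 higher, 41 lower). In the 7 clusterings tried for Il21 by class, the Xcl1-high class gave no value. Depth limits genes under 100 UMIs and classes under 20 cells.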

Other observations

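Of the tests in this part, those on wrongly sorted cells and on simulated slopes were chosen after the result was seen, and the genes followed by class were also chosen after their values were seen.

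The following shares by class hold for 1 clustering, and in 8 of 11 alternative clusterings the Xcl1-high cells formed no class of their own. Of 664 Cxcl13 UMIs, 334 (50.3%) lay in the 226 Xcl1-high cells, 36 of which had a UMI, and 170 (25.6%) in the 187 cycling cells. Of 796 Spp1 UMIs, 468 (58.8%) lay in Xcl1-high and 172 (21.6%) in Tfh-like cells. Cxcl13 draws CXCR5-bearing B cells and Tfh cells, and Spp1 encodes osteopontin. Penk, which encodes the opioid precursor proenkephalin, was spread over Th1- and Tr1-like (38.8% of its UMIs), Tfh-like (27.0%) and Xcl1-high cells (26.5%). By level, Penk was highest in the Xcl1-high cells, where it is a leading gene, at 311 CPM. It was at 189 CPM in Th1- and Tr1-like and 86.8 CPM in Tfh-like cells of the Venus-positive library. Th1- and Tr1-like cells held 210 of 326 Foxb1 UMIs and 198 of 266 Cdkn2b UMIs. Tfh-like cells held 70.4% and cycling cells 16.5% of Sostdc1 UMIs.

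Il10 came from different cells in the 2 sorts. In the Venus-positive library 781 of 876 Il10 UMIs (89.2%) lay in Th1- and Tr1-like cells, in 227 of 775 cells, and 3 of these 775 had a Foxp3 UMI. Il10 is itself among the leading genes of that cluster, so this share follows in part from how the class was formed. In the Venus-negative library 146 of 205 (71.2%) lay in Treg-like cells. At 2400 UMIs per cell, Il10 was seen in 12.6% of the 470 Venus-positive cells with an Il21 UMI (9.70 to 15.9) and in 6.90% of the 1825 without (5.78 to 8.17). Within Th1- and Tr1-like cells these shares were 28.6% of 182 (22.1 to 35.7) and 20% of 519 (16.7 to 23.7). The 2 intervals overlap, which does not settle whether the shares differ. In Tfh-like cells they were 2.46% of 203 (0.804 to 5.65) and 0.698% of 859 (0.257 to 1.51). In Xcl1-high cells they were 0% of 39 (0 to 9.03) and 2.81% of 178 (0.918 to 6.43), too few cells to give a direction. Over all 470 and 1825 cells Maf, a transcription factor that promotes both cytokines, was seen in 74.5% (70.3 to 78.4) and 62.7% (60.5 to 65.0), and Cxcr5 in 10.4% and 10.2%. Maf was not alone: Pdcd1 was seen in 46.2% and 38.2%, Ifng in 27.2% and 20.2% and Izumo1r in 73.0% and 65.7%. Tcf7 (34.3% and 39.2%) and Ccl5 (18.7% and 23.1%) were lower. These shares were not split by class, and no link of Maf to Il21 or Il10 was tested.

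The libraries filled different clusters, with 96.7% of cells in a cluster in which their own library held the majority. A difference in UMIs per cell would end this after thinning to 1 depth, but 96.1% of cells were then still in such clusters. A shift of the whole library was tested by the slope of the log2 ratio within a cluster against that between whole libraries, over genes not used to cluster, where a median of at least 0.8 would speak for it and at most 0.5 against. The median slope over 3 clusters was 0.449 (interval over genes 0.378 to 0.491), from 0.259, 0.477 and 0.449, whereas counts simulated with the full shift gave 1.00 at this depth. These values argue against a shift that is even over all cells of a library as the whole cause, although the way to take the spread and the simulation were settled after the slopes were seen, and the intervals of 2 single clusters reach 0.548 and 0.511. A partial shift, or one that is uneven among cells and spared the 37, 55 and 27 minority cells of these clusters, may remain, since library and sort gate coincide.

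Most Venus-positive cells, 1694 of 2499, had no Il21 UMI. Of these cells, 28 lay in clusters with a Venus-negative majority, which held 33 Venus-positive cells in all. Il21 took no part in clustering, so wrongly sorted cells with the profile of those clusters would be placed there. The count argues against such cells as most of the 1694, unless a library shift kept them apart. If at least 50% of the 1694 were an even draw of Venus-negative cells, naive or central memory genes would have at least 0.5 times their Venus-negative CPM. A value of at most 0.2 would speak against it. The median over 14 genes was 0.123, with an interval over genes of 0.0523 to 0.238. That interval lay below 0.5. The outcome was set in advance by the whole Venus-positive library, in which the naive list already had a median log2 ratio of -3.17. These cells are 1694 of its 2499, so their median could not have reached 0.5. The list result itself speaks against an even draw of at least 50%, and this test adds no separate evidence. The interval passed the lower bound of 0.2, so wrong sorting of a smaller share was not excluded by this test. Of the 14 genes, 11 had an interval below 0.5, and Tcf7 (1.00) and Ms4a4b (0.709) were above it. Wrongly sorted cells of other kinds than naive ones would also escape the test on naive genes. The count by cluster above covers those of the Treg-like and Il7r-high kinds. If a low level that is even within a cluster were merely sampled, the share with a UMI at 2400 UMIs per cell would be 24.1%, and 20.5% was observed, or 85.1% of that share (78.3 to 92.2). This lies between the bounds set beforehand, 90% or more for even sampling and 75% or less against it. The interval still lay below the full Poisson share, so Il21 UMIs were less even among cells of a cluster than a Poisson draw gives. Over all these cells their variance was 1.52 times their mean, with up to 8 in a cell, which includes differences between clusters. Uneven Il21 transcription among reporter-positive cells, or Venus protein that outlasts the RNA, may add to sampling, and neither cause was tested.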
